A study of Mus musculus with 20 samples.

How the data were processed

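Total RNA from the lungs of 20 C57BL/6 mice, an inbred laboratory strain, was measured on MA10 arrays, 1 array per mouse. Per the labels' protocols, RNA was extracted with acid guanidinium thiocyanate and phenol-chloroform, and the target was labelled with 33P, a radioactive isotope of phosphorus, by reverse transcriptase. Each array therefore gave 1 channel. Scanner, image software, membrane lots and hybridisation dates are not given in the sources used here.

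Per the file headers, each deposited scanner file gives 1 signal median and 1 local background median for each of 9600 spots, both as intensity on a linear scale without normalization. The authors' deposited series table holds intensity values of the same arrays. Set against the scanner files, its values equal signal minus background divided by the array's median of that difference, for 95.9% to 97.7% of spots per array within a relative tolerance of 0.001, and 217 values lie under 0. Its column medians lie between 0.999 and 1. It is not on a log scale and is not centred per spot. Rows of the table match the scanner files by their order in the file. The table columns of radiation replicates 4 and 5 hold each other's scanner values (18 of the 20 columns match their own array), so the scanner files were used for the main values. Both arrays belong to 1 group, and no comparison between whole groups changes with the exchange. The table holds 0 columns of other samples.

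Samples were grouped by the treatment in the labels into untreated, flaxseed, radiation, and flaxseed with radiation, with 5 mice each. The labels number the mice 1 to 20 and do not pair mice across groups. No 2 arrays held identical values.

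Background was corrected by normexp with an offset of 50, arrays were brought to a common distribution by quantile normalization, and values were taken as log2. The offset shrinks log2 changes of dim spots, since median signal above background was only 59.4 to 105.1 per array. All 4 groups entered 1 linear model per spot with limma 3.58.1 in R 4.3.3, with 16 residual degrees of freedom and empirical Bayes moderation (2.75 prior degrees of freedom). Two-sided p-values were adjusted by Benjamini-Hochberg over the 9600 spots, with a threshold of 0.05. The comparisons were 5 pairs of groups, the interaction of diet and radiation, and each treatment averaged over the other. Intervals are 95% intervals from the model. Control, blank and duplicate spots are not marked in the files, so all 9600 spots were tested as separate probes.

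The tables used here do not pair spot numbers with genes, and the number in a spot name is a position, not a gene identifier. The mouse gene table held for this work shares no identifier with the spots. The 40 gene lists fixed before the data were examined, and the genes chosen in advance by name, could therefore not be applied, and no list test was run. The rule for named items was applied to spots without its requirement of a gene symbol. For each comparison it took the largest rises and the largest falls among spots that passed, and where under 5 passed also the smallest p in each direction. At most 2 spots per direction were kept.

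Distances between groups were added after the data were seen. For each pair of groups, the mean over spots of the squared difference of group means was taken, with arrays centred over spots, and the part expected from the spread within groups was subtracted. Its exact one-sided test used the 126 splits of 10 arrays into 5 and 5, with Benjamini-Hochberg adjustment over 6 pairs. Covariances of changes between comparisons were tested two-sided by exact exchange of labels (63504 assignments), or by 100000 random assignments where comparisons shared the untreated arrays. Position was read from the spot numbers, which form 16 blocks of 24 rows and 25 columns; that this is the printed layout is an assumption.

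The limma fit was tested on simulated arrays with 200 of 9600 spots changed in the comparison of flaxseed with radiation against flaxseed. Of the changed spots it recovered 5.97% at a log2 change of 0.5, 28.4% at 1 and 60.6% at 1.5. It made 2 calls among unchanged spots there, and 0 calls where radiation against untreated held no change. In this setting most changes of 2-fold (log2 1) or less, and many at a log2 change of 1.5, thus passed unseen with 5 arrays per group. Changes were planted in signal above background, before the offset, which shrinks them. A larger number of changed spots would also loosen the threshold. The recovered shares therefore do not carry over directly to the log2 changes reported below.

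Alternatives were median scaling, cyclic loess, the authors' table values, no background correction, background subtraction, leaving out the dimmest 33.3% of spots, empirical Bayes with trend and robust options, array weights, fits of only the groups compared, a threshold of 0.1, and leaving out each array in turn. For subtraction and for the table, values under the 1st percentile of positive values were set to it. Removal of column, row and block means, and a fit without the pair of arrays with the strongest row effect, were added after the data were seen. A batch term was not fitted, since no batch is given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.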

Results

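The series measured RNA levels in mouse lung in a design that crossed diet and thoracic radiation. Mice received a diet with 10% flaxseed for 21 days, a dose of 13.5 Gy to the chest with tissue taken 48 hours later, both, or neither. Flaxseed is the seed of the linseed plant. Each of the 4 groups held 5 mice, with 1 array of 9600 spots per mouse. The files do not pair spots with genes, so results are given for spots by number.

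Median signal per array ranged from 75.3 to 125.8 and median local background from 15.02 to 23.81 in scanner units. The median ratio of signal to background lay between 4.65 and 6.53. Between 13.1% and 18.5% of spots were under 2 times their background, and 0.74% to 1.59% were at or under it. Median signal over background was 5.56 ± 0.655 (SD, n = 5) in untreated lungs, 5.5 ± 0.347 with flaxseed, 5.4 ± 0.723 with radiation and 5.84 ± 0.56 with both. Correlations of log2 values across spots were 0.95 to 0.975 for 40 pairs of arrays within groups and 0.924 to 0.977 for 150 pairs between groups; spots are not independent replicates. Precision was limited by the 5 arrays per group. The median standard error of a log2 difference between groups was 0.142, and the median 95% interval reached 0.297 to either side.

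The first principal component held 23.4% of the variance and placed the flaxseed arrays apart from the others. Their scores averaged 20.7 ± 3.79 (SD, n = 5), against 1.46 ± 5.75 for untreated arrays. Arrays of irradiated mice lay at the opposite end, at -10.8 ± 5.03 without flaxseed and -11.4 ± 3.89 with it.

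**Figure D1:**
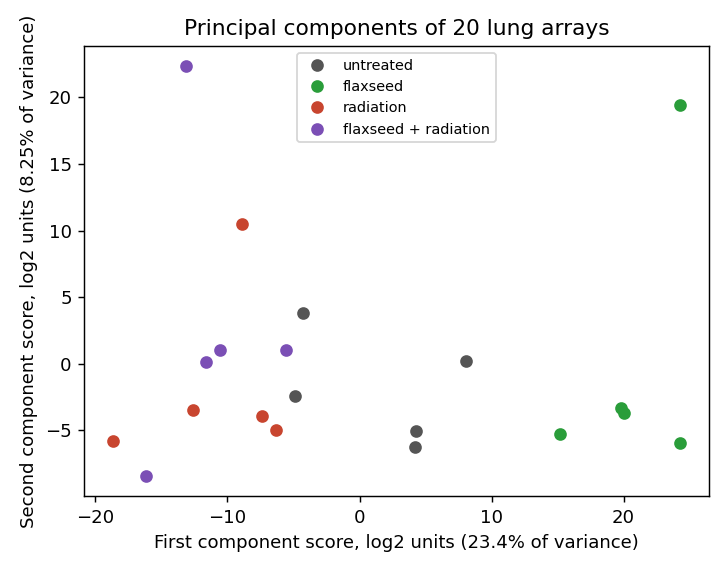
Scores of the 20 arrays on the first component (x axis, 23.4% of variance) and the second component (y axis, 8.25% of variance), in log2 units, with 1 point per array coloured by group. Flaxseed arrays score 15.2 to 24.3 on the first component, and every array of irradiated mice scores under 0.

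Radiation without flaxseed was compared with no treatment to find what thoracic radiation alone changed after 48 hours. Few spots passed the test, and those with the largest changes among them fell. Spot gene6591 fell from 12.7 ± 0.3 to 10.56 ± 0.46 (log2, SD, n = 5), a log2 change of -2.13 with a standard error of 0.39 (limma adjusted p = 0.0365). Spot gene9516 fell from 13.5 ± 0.3 to 11.39 ± 0.32, a change of -2.11 with a standard error of 0.36 (limma adjusted p = 0.0334). Spots gene3410 and gene2520 rose by 0.54 ± 0.1 and 0.5 ± 0.08 (log2, SE), and gene3410 was a dim spot, with a lowest group median of 2.99 times background. Under other settings these log2 changes ran from 0.45 to 1.19 for gene3410 and from 0.48 to 0.75 for gene2520. For each of these 4 spots all 5 irradiated arrays lay beyond all 5 untreated arrays, which the way they were picked largely fixes. In total 9 of 9600 spots passed in limma, 3 higher and 6 lower, and 734 had an unadjusted p under 0.05. Leaving out untreated replicate 3 or 5, or radiation replicate 1, 2, 3 or 4, each brought the count to 0. It was 5 without untreated replicate 2 and up to 33 under other settings, with 2 higher and 17 lower under median scaling, 3 and 16 under cyclic loess, 3 and 2 with the authors' table, and 2 and 29 without background correction. Over all spots together, the groups differed by a root mean square of 0.135 (log2, spread within groups removed), more than in any other split of the 10 arrays (exact permutation p = 0.00794, adjusted 0.0119). As a mean square this was 0.0182, and with the authors' table it was 0.0544 (exact permutation p = 0.0238), no longer beyond every other split. The authors' table carries no offset and no quantile normalization, so these 2 sizes are not on the same scale.

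Flaxseed without radiation was compared with no treatment to find what the diet alone changed. Spot gene4884 rose from 9.83 ± 0.49 to 10.91 ± 0.24 (log2, SD, n = 5), a change of 1.08 with a standard error of 0.2 (limma adjusted p = 0.0241). Spot gene5478 rose by 1.03 ± 0.21 (log2, SE). Its call held in 2 of 10 fits with a single array left out, against 6 of 10 each for gene4884, gene1092 and gene5063. Spot gene1092 fell from 13.53 ± 0.23 to 12.19 ± 0.55, a change of -1.34 with a standard error of 0.23 (limma adjusted p = 0.0241), and gene5063 fell by 1.28 ± 0.23 (log2, SE). All 5 flaxseed arrays lay in the direction of the change from the untreated mean for all 4 spots, which the way they were picked largely fixes. For gene5478 the groups overlapped, with untreated arrays up to 10.1 and flaxseed arrays from 9.9. In limma 42 spots passed, 19 higher and 23 lower, with a median absolute log2 change of 0.81, and 1277 had an unadjusted p under 0.05. Of these 42, 32 lay among the brightest 1920 spots. The count was between 3 and 50 when single arrays were left out, with 3 without untreated replicate 4, flaxseed replicate 2 or flaxseed replicate 4, 6 without untreated replicate 1, and 20 to 24 without untreated replicate 2 or 5 or flaxseed replicate 3. It was 2 without the pair of arrays with the strongest row effect and 81 without the dimmest spots. The split moved to 5 higher and 31 lower under median scaling, and to 1 higher and 8 lower both with the authors' table and with background subtraction. The groups differed by a root mean square of 0.189 (exact permutation p = 0.00794, adjusted 0.0119).

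Radiation on the flaxseed diet was compared with flaxseed alone to find what radiation changed in mice fed flaxseed. This comparison held the most changed spots. Spot gene6982 rose from 12.28 ± 0.72 to 14.22 ± 0.31 (log2, SD, n = 5), a change of 1.95 with a standard error of 0.28 (limma adjusted p = 0.000883). Spot gene2661 rose from 11.43 ± 0.27 to 13.12 ± 0.54, a change of 1.69 with a standard error of 0.27. Spots gene1091 and gene0016 fell, with log2 changes of -2.75 ± 0.44 and -2.72 ± 0.46 (SE), or 6.73-fold and 6.57-fold, with limma adjusted p of 0.00164 and 0.00238. The groups did not overlap for any of these 4 spots, which the way they were picked largely fixes. In untreated lungs gene6982 stood at 13.51 ± 0.32 and gene2661 at 12.44 ± 0.57, between the values of the groups compared.

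In all, 730 spots passed in limma for radiation on the flaxseed diet, 436 higher and 294 lower. With flaxseed alone, 7 of the 436 and 284 of the 294 had a higher mean than untreated (median log2 changes -0.435 and 0.45). With both treatments, 415 of the 436 and 27 of the 294 had a higher mean than untreated (medians 0.28 and -0.264). Each of these comparisons shares arrays with the 1 that picked the spots, which alone tilts them this way. The median absolute log2 change of the 730 was 0.742, and 118 changed more than 2-fold. Of the 730, 464 lay among the brightest 1920 spots and 12 among the dimmest 1920. The SD of the log2 change over spots was 0.624 among the brightest and 0.0869 among the dimmest. The offset shrinks changes of dim spots, and its part in this skew of calls was not tested. The root mean square difference was 0.294 (exact permutation p = 0.00794, adjusted 0.0119). Without flaxseed replicate 4 the count was 448, and without the pair of arrays with the strongest row effect it was 352. The split was 573 higher and 173 lower under median scaling and 418 higher and 120 lower with the authors' table.

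**Figure D2:**
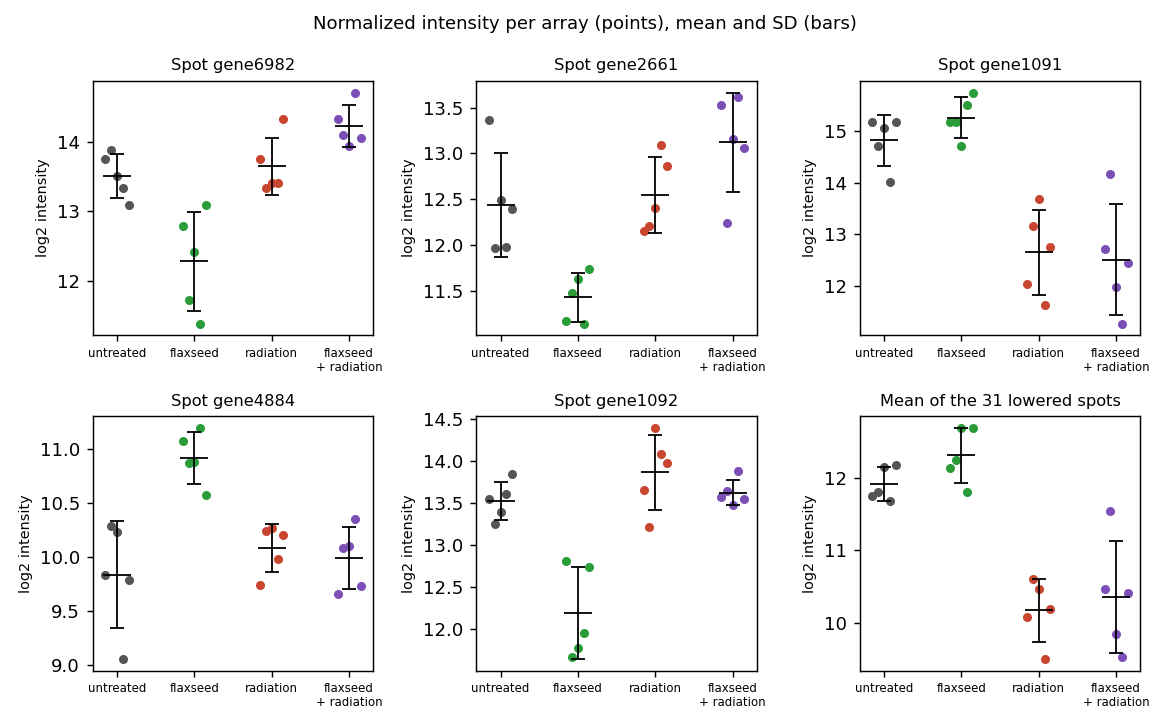
Normalized log2 intensity per array (y axis) by group (x axis) for 5 named spots and for the mean of the 31 spots that were over 2-fold lower after radiation on both diets. Points are arrays, horizontal marks are means and bars are SD over 5 arrays; the 31 spots average 11.91 in untreated lungs, 12.31 with flaxseed, 10.17 with radiation and 10.36 with both.

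Radiation changes on both diets were set against each other over the same spots, using different arrays for each. Of the 436 spots that rose on the flaxseed diet, 355 (81.4%) had a higher mean after radiation without flaxseed. Of the 294 that fell, 93 (31.6%) did. The changes correlated across spots with r = 0.457, and the covariance was 0.0333 (exact permutation p = 6.3e-05 over 63504 assignments). With the spread within groups removed, r was 0.84 and the slope of the flaxseed-diet change on the other was 1.83. Of the 6 spots that fell without flaxseed, 5 also fell on it, where 0.184 would be shared by independent lists. Of the 3 that rose, 1 also rose, where 0.136 would be shared.

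A set of 31 spots was over 2-fold lower after radiation on both diets, while 0 spots were over 2-fold higher on both. This set was picked after its values were seen. It holds gene6591, gene9516, gene1091, gene0016 and gene0066, which all lie in column 16 of the spot number. These may therefore not be separate responses to radiation. Its median log2 change was -1.91 without flaxseed and -2.01 with it. All 31 passed in limma for radiation averaged over diets, which the way the set was picked largely fixes. The mean of the 31 was 11.91 ± 0.23 (log2, SD, n = 5) in untreated lungs, 12.31 ± 0.38 with flaxseed, 10.17 ± 0.43 with radiation and 10.36 ± 0.77 with both. Flaxseed differed from untreated by 0.4 ± 0.2 (SE; exact permutation p = 0.0794, adjusted 0.238), which did not pass. The set was bright, and its dimmest member ranked at 74.6% of all spots by mean intensity.

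**Figure D3:**
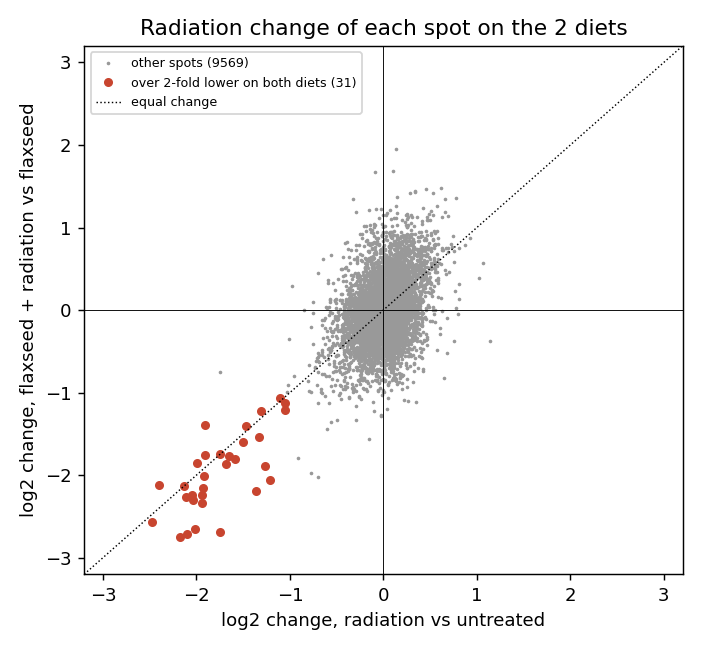
Log2 change of each of 9600 spots for radiation against untreated (x axis) and for flaxseed with radiation against flaxseed (y axis); the dotted line marks equal change. The 31 red points are over 2-fold lower on both diets, and across all spots r is 0.457.

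Flaxseed was also compared with no flaxseed among irradiated mice, to find whether the diet changed the irradiated lung. No spot passed in limma (0 of 9600), 518 had an unadjusted p under 0.05, and the smallest adjusted p was 0.508. The smallest p among higher spots belonged to gene8744, at 0.5 ± 0.12 (log2, SE), and among lower spots to gene4462, at -0.51 ± 0.1, and neither passed. With the spread within groups removed, the mean square difference was -0.00183, and 97 of 126 splits gave as much (exact permutation p = 0.77). Background subtraction gave 2 spots, both lower. Flaxseed changes with and without radiation had r = -0.047 across spots and a covariance of -0.00199 (exact permutation p = 0.456). The covariance was -0.00609 without radiation replicate 5 (exact permutation p = 0.0118), and of opposite sign without radiation replicate 3 (0.000368) or 4 (7.55e-05). Of the 19 spots that rose with flaxseed alone, 10 had a higher mean with flaxseed among irradiated mice, and of the 23 that fell, 12 did.

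Both treatments together were compared with neither. Spot gene3410 rose by 0.62 ± 0.1 (log2, SE), with 0.47 to 1.34 under other settings. It had also risen with radiation alone, a comparison that shares the untreated arrays. Spots gene6121 and gene7226 fell, at -1.43 ± 0.23 and -1.12 ± 0.17. These 3 were the spots that passed in limma (adjusted p = 0.0257 for gene3410 and gene6121, 0.0236 for gene7226), and 728 had an unadjusted p under 0.05. The count was between 0 and 24 when single arrays were left out and reached 36, 4 higher and 32 lower, without background correction. It was 0 without untreated replicate 3 or flaxseed and radiation replicate 5, 1 without replicate 1 of that group, 24 without its replicate 2, and 10 without untreated replicate 4. The root mean square difference was 0.125 (exact permutation p = 0.0159, adjusted 0.0191). Its mean square of 0.0157 was 0.0248 with the authors' table and did not pass there (exact permutation p = 0.0952).

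The interaction of diet and radiation asked whether the radiation change differed between diets. No single spot passed in limma (0 of 9600), 971 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0616, for gene4007 at -1.31 ± 0.21 (log2, SE). Over all spots together, the corrected mean square of the difference between the radiation changes was 0.0379, and exchange of diet labels within irradiated and unirradiated mice gave as much in a share of 0.00485 of 63504 assignments (exact permutation p). The count of spots was 13 without radiation replicate 5, 3 without untreated replicate 3, 1 without flaxseed replicate 1 and 2 without flaxseed replicate 3. Among 11 other settings it stayed at 0 in 6. It was 6, all higher, with median scaling and 9, 6 higher and 3 lower, without the dimmest spots. With background subtraction and with position removed it was 1 each, and it was 15 at a threshold of 0.1.

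Averaged over both diets, radiation changed 493 spots in limma, 311 higher and 182 lower, with 1896 at an unadjusted p under 0.05. Spots gene6958 and gene6982 rose by 1.07 ± 0.22 and 1.04 ± 0.2 (log2, SE), and gene0066 and gene1091 fell, at -2.52 ± 0.4 and -2.46 ± 0.31. Spots gene6958 and gene6982 lie beside each other in the numbering, and whether signal spread between them was not tested. Without flaxseed, gene6958 changed by 0.78 ± 0.31 and gene6982 by 0.13 ± 0.28, and neither passed (limma adjusted p = 0.549 and 0.969). On the flaxseed diet their changes were 1.36 and 1.95. Without flaxseed, gene0066 changed by -2.47 ± 0.56 and gene1091 by -2.17 ± 0.44, also without passing (limma adjusted p = 0.0968 and 0.0615). Of the 493, 40 changed more than 2-fold. Among the 311 higher spots, 306 had a higher mean with radiation alone than untreated, and 17 a higher mean with flaxseed alone. Among the 182 lower spots these numbers were 3 and 155. Both comparisons share arrays with the average. The split was 388 higher and 145 lower under median scaling and 296 higher and 107 lower with the authors' table. Averaged over radiation, flaxseed changed 7 spots, 2 higher and 5 lower, with 873 at an unadjusted p under 0.05. Spots gene1671 and gene2825 rose by 0.48 ± 0.09 and 0.37 ± 0.07, and gene5063 and gene3527 fell, at -0.93 ± 0.16 and -0.65 ± 0.12. Of 10 other settings, the call held in 0 for gene2825 (log2 change 0.27 to 0.74), 2 for gene3527, 3 for gene1671 and 7 for gene5063. The count of 7 was 1 to 9 when single arrays were left out, and 3 or fewer without any 1 of 13 arrays, that is, any but untreated replicate 3, flaxseed replicate 5, radiation replicates 1, 2 and 4, and flaxseed and radiation replicates 1 and 4.

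Values varied with position as read from the spot numbers, and this variation differed by group. That the numbers give the printed layout is an assumption. The column of the spot number accounted for 6.19% of the variance of the radiation change on the flaxseed diet, 5.31% of the flaxseed change and 1.9% of the radiation change without flaxseed. The highest of 1000 shuffles gave 0.581%, 0.593% and 0.551%. The row accounted for 7.9% of the variance between diets among irradiated mice, where the highest shuffle gave 0.562%, and for 2.74% of the radiation change without flaxseed, more than the column did there. Column means of flaxseed arrays shifted by up to 0.113 (log2, column 25) above and -0.112 (column 13) below the mean of all arrays. With column, row and block means removed, 773 spots passed for radiation on the flaxseed diet, 452 higher and 321 lower, 67 for flaxseed and 22 for radiation alone.

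**Figure D4:**
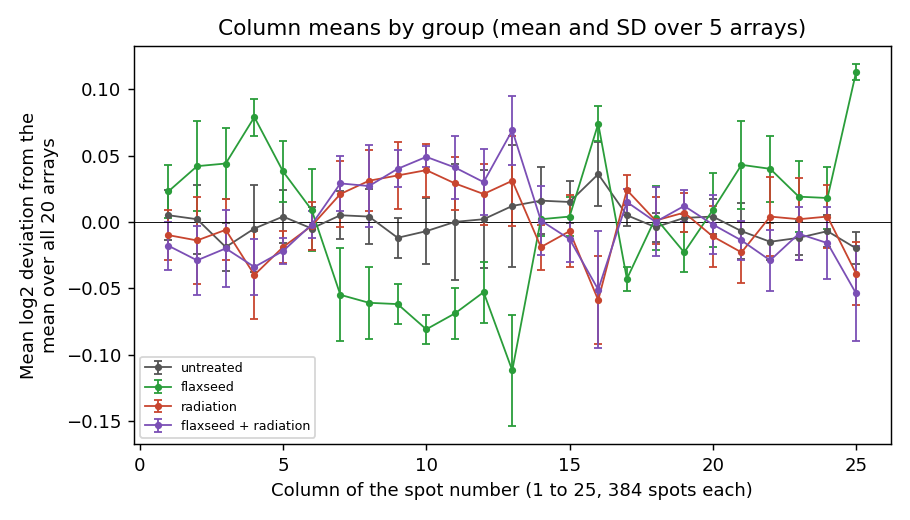
Mean log2 deviation of each column of the spot number (x axis, columns 1 to 25 of 384 spots) from the mean over all 20 arrays (y axis), by group, with SD over 5 arrays. The flaxseed arrays reach 0.113 in column 25 and -0.112 in column 13, while the other groups stay between -0.059 and 0.069.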

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

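In this part the tests on position, cyclic loess, batch, film or washing and print run were chosen after the results were seen; the tests on single arrays, brightness, the difference between diets and other splits of the arrays were written before their results. Of 140 sets of 5 arrays examined for a lone value far from the rest, 3 had one, where chance gives about 7.

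The row of the spot number accounted for 19.7% of the variance in flaxseed and radiation replicate 1, against 2.03% to 5.26% in the other 4 arrays of its group. Spot gene0016 stood at 10.5 (log2) in radiation replicate 4, against 12 to 12.5 in the other 4. Spot gene4007 stood at 9.84 in untreated replicate 3, against 9.21 to 9.29 in the other 4.

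The radiation changes of spot gene9198 had opposite signs on the diets, at 0.42 without flaxseed and -0.73 with it in every irradiated array. The difference of -1.16 ± 0.2 (log2, SE) was tested and did not pass in limma (adjusted p = 0.0696).

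More spots passed for radiation on the flaxseed diet (730) than without flaxseed (9), and over all spots the changes differed with a corrected mean square of 0.0379 (exact permutation p = 0.00485). A single array did not account for the gap, since the lowest count over leave-outs was 448. Position as read from the spot numbers did not either, with 773 spots after its removal, nor did brightness-dependent normalization, with 694 under cyclic loess. The irradiated groups showed no detectable difference from each other (corrected mean square -0.00183, exact permutation p = 0.77), while the unirradiated groups differed (0.0357, exact permutation p = 0.00794). A membrane or hybridisation batch stays open and cannot be told apart from the groups, because none is given and the mouse numbers of all 4 groups form unbroken runs. A diet-dependent response to radiation, or a batch that holds the flaxseed arrays, may each account for it.

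The flaxseed arrays shared a pattern over columns of the spot number. Brightness did not account for it, since column held 6.18% of the variance of the radiation change on the flaxseed diet after a smooth curve in brightness was removed and 6.19% before. Uneven film or washing on single arrays did not either, since the lowest correlation of column means between any pair of flaxseed arrays was 0.799; the ranges were 0.307 to 0.913 with flaxseed and radiation, 0.0138 to 0.87 with radiation and -0.453 to 0.755 without treatment. The pattern did not go with the diet as such, since arrays of mice given flaxseed and radiation averaged -0.054 (log2) in column 25 and 0.069 in column 13, against 0.113 and -0.112 with flaxseed alone. A print run of membranes shared by the flaxseed arrays is a candidate explanation that cannot be told apart from that group, since no print run is given. Such a print run would not account for all of the column effect. Column also held 1.9% of the variance of the radiation change without flaxseed (highest shuffle 0.551%), where no flaxseed array enters.

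Chance assignment of arrays was tested on 100 splits for each count, the real one included. With all arrays, only the real split gave as many for radiation alone (9 spots, highest other 3) and flaxseed alone (42, highest other 1). The same held for radiation on the flaxseed diet (730, highest other 8) and radiation averaged over diets (493, highest other 5). It also held for flaxseed averaged over radiation (7, highest other 3). A share of 1 in 100 is the smallest this test can give, and no adjustment was made over the counts tested. Chance is thus unlikely for these counts but not excluded. For both against neither (3 spots), 2 of the 100 splits gave as many, the real one and another with 4, so the share is small but the count is not the highest. Chance is therefore not firmly set aside there. The splits were not repeated under other settings, and 3 of these counts reached 0 in some. That for both against neither was 0 with only the groups compared and without untreated replicate 3 or the replicate 5 given both. That for radiation alone was 0 in 6 of 10 fits with a single array left out. Both were 0 without the pair of row-affected arrays. That for flaxseed averaged over radiation was 0 with the authors' table and 1 in 5 of 20 fits with a single array left out. For these 3 the splits speak only for the counts with all arrays. For flaxseed among irradiated mice (highest other 2) and the interaction (highest other 43) the real count was 0, so all 100 splits gave as many by construction and the splits decide nothing. The split with 43 parted irradiated from unirradiated mice except for untreated replicate 5 and radiation replicate 4, so it largely took up the radiation change.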

How the results depend on the processing

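The 2 settings on position and row effects, and all distances and covariances, were added after the data were seen. Of 48 distances under other settings 47 kept their side of the threshold, as did 32 of 32 covariances. Of 93 counts 48 stayed within a factor of 1.5 or at 0; named spots that passed kept direction and side in 184 of 245 values, and in 181 of 310 with single arrays left out, and reversed in 0. With single arrays left out, calls for radiation alone held in 0 of 10 fits for gene6591, 1 for gene3410, 2 for gene9516 and 4 for gene2520. The cause of a move was not tested. Dim spots limit the counts, since 13.1% to 18.5% of spots lay under 2 times background. List tests (with their alternatives) and a batch term were not run, since spots carry no gene names and no batch is given. No paired analysis was possible because the mouse numbers do not pair mice.

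For radiation alone (9), counts were 19 with median scaling, 19 with cyclic loess, 5 with the authors' table, 31 without background correction, 21 with subtraction, 30 without the dimmest spots, 24 with trend and robust, 19 with only the groups compared, 33 at a threshold of 0.1, 22 with position removed, and 0 without the pair of row-affected arrays. For flaxseed alone (42), they were 26 with loess, 9 with the table, 9 with subtraction, 81 without the dimmest spots, 24 with trend and robust, 116 at 0.1, 67 with position removed and 2 without the pair. For both against neither (3), they were 9, 7, 7, 36, 7, 28, 24, 5 (array weights), 0 (only the groups compared), 20 (at 0.1) and 0 (without the pair), the first 7 in the order of median scaling, loess, table, no correction, subtraction, dim spots, trend and robust. Its distance with the table was 0.0248 (exact permutation p = 0.0952), no longer past the threshold, over a range of 0.0144 to 0.0248. Other mean squares ranged from 0.0182 to 0.0544 for radiation alone, 0.0333 to 0.0825 for flaxseed alone, 0.0789 to 0.177 for radiation on the flaxseed diet, 0.0802 to 0.198 for radiation against flaxseed, and 0.0327 to 0.0862 for the difference between radiation changes. The covariance of the radiation changes ranged from 0.0312 to 0.0726, and that of flaxseed alone and radiation alone from -0.0307 to -0.0141.

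For radiation on the flaxseed diet (730), counts were 1165 at 0.1 and 352 without the pair; radiation averaged over diets (493) gave 873 at 0.1. Flaxseed among irradiated mice (0) gave 2 with subtraction. The interaction (0) gave 6 with median scaling, 1 with subtraction, 9 without the dimmest spots, 15 at 0.1 and 1 with position removed. Flaxseed averaged over radiation (7) gave 1, 2, 0, 2, 2 and 1 with median scaling, loess, table, no correction, subtraction, and trend and robust.

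Leaving out single arrays gave 0 to 9 for radiation alone, 3 to 50 for flaxseed alone, 0 to 0 for flaxseed among irradiated mice, 448 to 690 for radiation on the flaxseed diet, 0 to 24 for both against neither, 0 to 13 for the interaction, 370 to 535 and 1 to 9 for the averages of radiation and flaxseed. The covariance of flaxseed changes with and without radiation (-0.00199) went from -0.00609 without radiation replicate 5 (exact permutation p = 0.0118) to 0.000368 without radiation replicate 3 and 7.55e-05 without replicate 4, the last 2 of opposite sign. That of flaxseed alone and radiation alone (-0.0154) went from -0.0178 to -0.0112, and passed without flaxseed replicate 4 (-0.0162, permutation p = 0.0486).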

Other observations

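The test on neighbouring spots and that on shared untreated arrays were chosen after the results were seen. The 31 spots that were over 2-fold lower after radiation on both diets varied together within groups. The median pairwise correlation of their deviations from group means was 0.576 over the 20 arrays, above all of 10000 random sets matched on brightness (median -0.0062, 95th percentile 0.0251). The spots lay in 12 of the 16 blocks and 9 of the 25 columns, with 12 in column 16, 7 in column 15 and 4 in column 14, where an even spread would put 1.24 in each. The spots named as falls for radiation alone, on the flaxseed diet and averaged over diets all lay in column 16. Signal spreading from a neighbour was argued against, since 4 of the 31 had another of them beside them in the numbering, and the other 27 had a median correlation of 0.598. The neighbour test covers only spots beside each other, so it does not address why so many lay in columns 14 to 16, which was not tested. It may be that 1 transcript, related transcripts or 1 cell population lies behind several of these spots. Without gene names these, or an effect tied to the columns, cannot be separated here.

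Flaxseed alone and radiation alone tended to opposite signs over all spots, as a hypothesis that did not pass. Their changes share the untreated arrays, which alone would give a correlation of 0.5 and a covariance of 0.0144 in 100 simulations; the values seen were -0.0426 and -0.00228. With split controls, r ran from -0.36 to -0.0249 over 20 splits. With the noise of the shared arrays taken out, the covariance was -0.0154, below 99.6% of 100000 random assignments, but its size was not beyond the threshold in a two-sided permutation test (p = 0.0594). The 5 flaxseed arrays and the irradiated arrays lie at opposite ends of the first component. Within groups, the score on that component went with median signal over background (r = -0.525, permutation p = 0.0413; rho = -0.525, permutation p = 0.0386; 20 arrays, 1 relation examined). Without the 2 arrays farthest from the median of that ratio, r was -0.319, so the relation rests in part on those arrays. The quality of single arrays may thus be part of that component, while median signal over background of the groups differed by less than the spread within them. Another array measure, the percent of signal in the brightest 10 spots, did differ by group. It was 8.14 ± 0.938 (SD, n = 5) with flaxseed, 9.71 ± 0.808 untreated, 11.1 ± 0.826 with radiation and 10.7 ± 1.44 with both. Its relation to the component was not tested.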
